A study of Danio rerio with 6 samples.

How the data were processed

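Cells positive for cd41 were isolated from zebrafish embryos of 40 hours, RNA was extracted with a Zymo Quick-RNA microprep kit, and polyadenylated RNA was made into libraries at BGI with its low-input protocol, per the labels; the series design names an Illumina NovaSeq. Paired-end fragments per gene were counted by the authors with featureCounts 1.5.0-p1 against the Ensembl release 85 annotation of GRCz10, per the file headers, with both mates required to map, chimeric pairs excluded and no option for strand, multiple mapping or overlap set. Picard, Trim Galore, STAR 2.4.2a, DESeq2 and Cufflinks 2.2.1 are named, per the submitters' processing notes, without their roles. The deposited values are raw whole-number counts for 32105 Ensembl genes in 6 libraries, 3 per genotype, with no normalization. Because strand was not used and fragments shared by overlapping genes or copies were not counted, values of overlapping genes and of near-identical copies such as globins and gamma crystallins are uncertain. Of the counts, 23.9% to 36.9% fell on the 3 most abundant genes, which are 2 mitochondrial genes without a symbol and zgc:158463 on chromosome 5, and 21.3% to 30.7% on the mitochondrial genome.

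Identifiers were matched to symbols through a table of Ensembl gene names, which named 26269 of the 32105 genes and 17593 of the 18722 tested. Many of its symbols are upper-case orthologue symbols, and a symbol held by several genes is printed with its identifier. Members of the fixed gene lists were matched by symbol without regard to case, or, where that failed, by the orthologue symbol without the paralogue ending, leaving out symbols carried by more genes than the list names. The entry for the Notch ligand gene delta D was left unmatched, since its symbol met that of dihydrolipoamide dehydrogenase; this was done after the results were seen. Of 619 list entries 43 were not matched and 29 were ambiguous, and 484 genes were matched by symbol and 62 by orthologue symbol. The identifier that the name table pairs with ddx41 is not one of those in the count table used, so the planned comparison of the ddx41 level was not run and the gene is not reported here.

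In R 4.3.3, edgeR 4.0.16 was run with TMM normalization, filterByExpr at its defaults (minimum count 10, minimum total 15), a model of genotype, the quasi-likelihood F test (two-sided) and Benjamini-Hochberg adjustment over the 18722 genes kept. Standard errors are the log2 fold change divided by the square root of F. CPM are counts scaled to a common library size with the TMM factors, and means are given ± SD. Lists of at least 4 tested genes were tested on log2 CPM (prior count 2) with limma 3.58.1, by camera with a correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over 26 lists. For each list the genes passing over all genes tested and those adjusted over the list alone were counted. Shares of counts were compared by a two-sided exact permutation test of the difference of means, which cannot go below 0.1 here, adjusted over 3 classes. For genes with few counts in a genotype, the ratio over the group has an exact 95% binomial interval, and with 0 counts a floor of 3 counts over the group gives a bound. These intervals and floors cover counting error only.

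The comparison, gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named ddx41, then the 10 largest increases and 10 largest decreases among genes with adjusted p below 0.05, a mean log2 CPM of at least 1 and no overlap of the libraries, with at most 2 genes without a symbol per direction, and then up to 4 members of each list with the smallest p. A gene this rule names is not reported here. The alternatives were RLE size factors, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0 (Wald test), limma voom with sample weights, the replicate number as a block, each library left out in turn, and, for shares, a denominator without the other classes. No pair of libraries was alike within counting noise: the chi-square per degree of freedom over genes was at least 19.3 in every pair. A check for GC content was not made, since no genome sequence was used here.

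The scripts were tested on simulated counts for the 18722 genes, with the means and library sizes of the real data and 200 genes changed between mutant and wildtype. The test recovered 0% of 67 genes changed 2-fold, 28.4% of 67 changed 4-fold and 48.5% of 66 changed 8-fold, and 3.77% of the 53 genes called were unchanged ones. A planted spliceosome list was called, with 0 other lists, and 0 of 26 lists were called with none planted. Genes were simulated as independent, without the correlation within lists of the real data (estimated at 0.355 for the spliceosome list). These list results therefore do not carry over to correlated genes. The pass marks of the simulation were lowered after its first run, in which under 0.5 of the 8-fold changes were recovered. At this depth and replicate number a 2-fold difference in a single gene could therefore be missed. With 53 genes called in the simulation against 625 and 373 in the real data, its adjusted threshold was stricter. The percentages recovered are thus not those of the real data.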

Results

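Transcript levels were measured by RNA-seq in cd41-positive cells of zebrafish embryos, 40 hours after fertilization, from ddx41 mutants and from wildtypes. The cd41 gene, itga2b, encodes an integrin chain. Its fluorescent reporter marks blood stem and progenitor cells and thrombocytes, the fish counterpart of platelets. DDX41 is a DEAD-box RNA helicase whose human gene is mutated in some myeloid leukaemias. Each genotype had 3 libraries. Counts on genes totalled 14577735 to 15912260 per mutant library and 17001423 to 17639699 per wildtype library. Each mutant library was thus shallower than each wildtype library (n = 3 each, two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). The labels do not say that libraries came from separate clutches or sorts, so p-values measure only the spread between these libraries. The level of ddx41 itself was not analysed here, and the genotype labels were not checked against it.

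**Figure D1:**
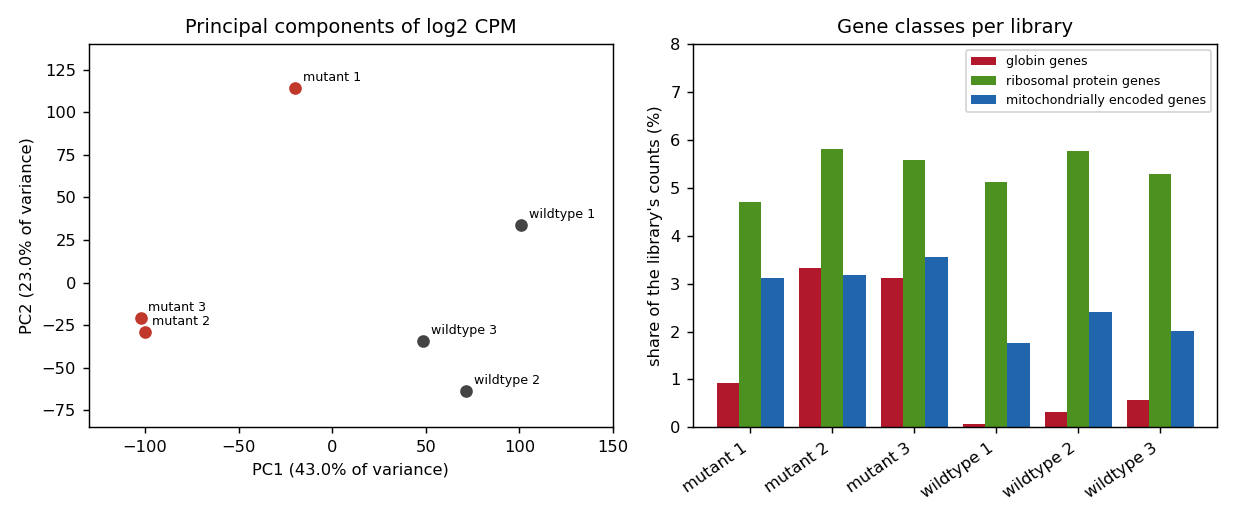
Left, the 6 libraries on the first 2 principal components of log2 CPM, with the percent of variance on each axis; right, bars giving the percent of each library's counts in globin, ribosomal protein and mitochondrially encoded genes. On PC1 (43.0% of the variance) the mutants lie below 0 and the wildtypes above it, on PC2 (23.0%) mutant replicate 1 stands apart, and globin genes take 0.919% to 3.33% of the mutant libraries and 0.0612% to 0.562% of the wildtype libraries.

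To determine which transcripts differ between ddx41 mutant and wildtype cells, 18722 genes were tested. Genes of the spliceosome, some DNA damage response genes and red blood cell genes rose in the mutants, while some myeloid and amino acid stress genes fell. The ubiquitin ligase gene mdm2 was 7.57-fold higher. The splicing factor genes PRPF31 and PRPF3 were 12.9-fold and 11.7-fold higher. CXCR4 (ENSDARG00000041959), a chemokine receptor gene of blood progenitors and leukocytes, was 8.18-fold lower. In all, 625 genes were higher and 373 lower (edgeR quasi-likelihood test, adjusted p below 0.05), of which 386 and 172 differed at least 4-fold. The libraries of the genotypes did not overlap in 623 and 373 of these genes, nor in 28.7% of all tested genes, where chance gives 10%. The counts depended on single libraries: they were 1135 and 832 without mutant replicate 1, 146 and 37 without mutant replicate 2, and 103 and 21 without mutant replicate 3. They were 51 and 11 without wildtype replicate 2, and 217 and 117 without wildtype replicate 3. DESeq2 called 1357 and 1223, and limma voom with sample weights 1460 and 1352.

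The largest increases included genes of the lens, of red blood cells and of channels. The gamma crystallins crygm2d13 and crygm2d1 are bulk proteins of the lens, and lim2.3 encodes a membrane protein of lens fibres. No wildtype library held a count of crygm2d13 (ENSDARG00000057460, chromosome 9, 22280292 to 22281456, GRCz10), against 205 over the mutants. It was at least 84.9-fold higher, with a floor of 3 counts over the group (edgeR adjusted p = 0.0182). With 462 counts against 1, the ratio for crygm2d1 was 574 (95% counting interval 103 to 22731). The ratio was 339 (60.4 to 13452) for the water channel gene aqp8a.2, 231 (41.0 to 9180) for si:ch73-15n24.1 and 152 (41.5 to 1259) for lim2.3. Log2 fold changes were 7.36 ± 0.89 (SE) for si:ch211-5k11.8, 6.96 ± 1.15 for si:ch211-114c12.5 and 6.95 ± 1.12 for the ATP-gated channel gene P2RX4 (ENSDARG00000042452). They were 7.17 and 6.81 for globin genes, both with the orthologue symbol HBE1 (ENSDARG00000097238 and ENSDARG00000089087). The HBE1 genes overlap on chromosome 3, and crygm2d1 spans 22335673 to 22528713 among similar genes, so their separate counts are uncertain. Beside the HBE1 genes, of which ENSDARG00000089087 ends at 54849708, si:ch211-5k11.8 spans 54850464 to 54851364. It was not counted in the globin class. All 4 wildtype counts of P2RX4 lay in wildtype replicate 3 and all 5 of HBE1 (ENSDARG00000089087) in wildtype replicate 2. Without those libraries these genes were at least 120-fold and 155-fold higher, with a floor of 3 counts over the group. The wildtype counts of si:ch211-114c12.5 fell from 9 to 1 without wildtype replicate 2, where its ratio was 894 (95% counting interval 160 to 35344) against 141. With 0 wildtype counts left and the same floor, crygm2d1 was at least 125-fold higher without wildtype replicate 1, and aqp8a.2, si:ch73-15n24.1 and lim2.3 at least 72.9-fold, 49.7-fold and 65.2-fold higher without wildtype replicate 3. Without wildtype replicate 2 none of these 10 genes passed (adjusted p = 0.0539 to 0.0983). Without mutant replicate 3 the mutant mean fell from 4.65 to 2.86 CPM for crygm2d13, 10.6 to 6.50 for crygm2d1, 5.94 to 3.88 for aqp8a.2 and 11.5 to 5.28 for HBE1 (ENSDARG00000097238). Without mutant replicate 2 it fell from 22.4 to 10.8 CPM for si:ch211-114c12.5. Some also missed the threshold without mutant replicate 2 (up to 0.0812), mutant replicate 3 (up to 0.0866) or wildtype replicate 3 (up to 0.0588).

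The largest decreases included VSX1, a transcription factor gene of retinal neurons, and pou4f4, of the POU family. VSX1 held 1 count over the mutants and 706 over the wildtypes, a ratio of 568 (95% counting interval 102 to 22466). Wildtype replicate 1 alone reached 34.6 CPM, against 0.879 and 2.11 CPM in the other wildtype libraries, and without it VSX1 did not pass (edgeR adjusted p = 0.0888). The ratio was 319 (56.9 to 12615) for igsf9ba, 246 (84.0 to 1196) for ENSDARG00000099781 and 138 (37.9 to 1144) for pou4f4. Without wildtype replicate 1 the wildtype mean fell from 7.06 to 3.85 CPM for igsf9ba, 16.8 to 7.65 for ENSDARG00000099781 and 6.18 to 3.59 for pou4f4. The ratio was 126 (42.9 to 613) for the ribonuclease gene rnaset2l and 103 (28.2 to 855) for si:ch211-76l23.4, whose wildtype mean fell from 4.93 to 3.08 CPM without wildtype replicate 2. With 1 mutant count left, the ratio was 269 (48.1 to 10657) for rnaset2l without mutant replicate 1 and 477 (85.5 to 18873) for ENSDARG00000099781 without mutant replicate 2. With 0 left and a floor of 3 counts, igsf9ba and si:ch211-76l23.4 were at least 68.6-fold and 44.4-fold lower without mutant replicate 2, and VSX1 and pou4f4 at least 121-fold and 59.0-fold lower without mutant replicate 3. The decrease of zgc:136930 (ENSDARG00000055192, chromosome 2, 32796920 to 32807669) passed without any 1 library, at 0.272 ± 0.0987 CPM in mutants and 19.8 ± 4.32 CPM in wildtypes (SD, n = 3; log2 fold change -6.14, edgeR adjusted p = 0.00225). Lower too were si:dkey-106n21.1 (-5.68 ± 1.15 SE), CYB561A3 (ENSDARG00000028257, -5.33 ± 1.27) and mlphb (-5.28 ± 1.25), a gene of pigment granule transport. These 3 were highest in wildtype replicate 1, at 122, 88.4 and 36.2 CPM, and their wildtype means without it were 17.4, 10.4 and 5.42 CPM. Without it CYB561A3 and mlphb did not pass (adjusted p = 0.103 and 0.112), and without mutant replicate 1 CYB561A3 was at -6.67. Each of the 10 but zgc:136930 missed the threshold without mutant replicate 2 (up to 0.16), mutant replicate 3 (up to 0.151) or wildtype replicate 2 (up to 0.127).

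To determine whether genes known to act together moved together, 26 gene lists were compared. By camera with a preset correlation, 6 lists were higher in the mutants and 3 lower. None of these 9 was called with an estimated correlation, where the smallest adjusted p was 0.596, and fry called 2, the spliceosome and DNA damage response lists. Other splits of the same 6 libraries into 3 and 3 gave up to 13 lists with the preset correlation, so counts of single genes are given beside each list. Those splits hold both genotypes on both sides, so they are not free of a genotype difference. Of 65 named genes that passed, 9 did so without any 1 library.

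**Figure D2:**
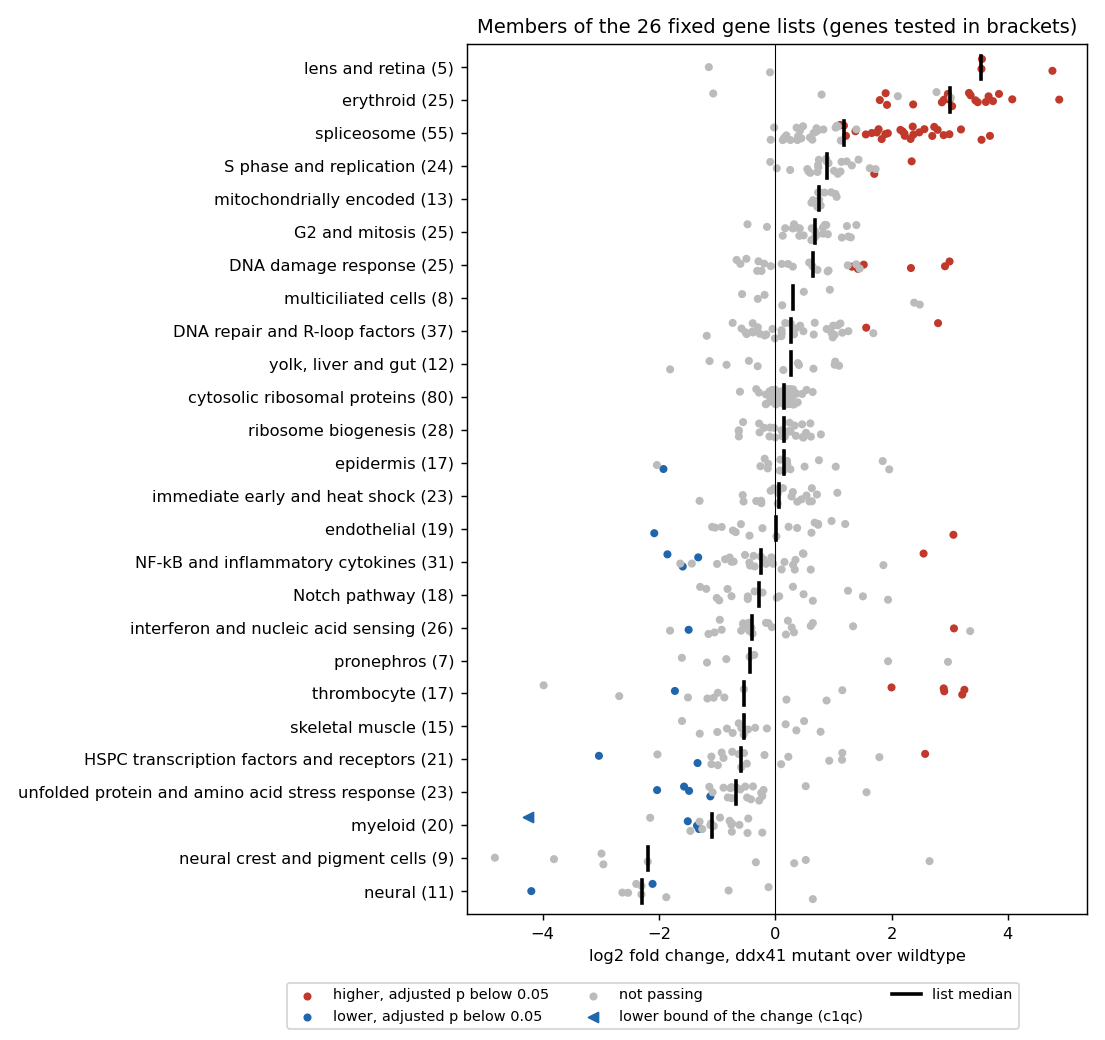
Each point is a tested gene of a fixed list, placed by its log2 fold change of ddx41 mutant over wildtype (horizontal axis), with lists ordered by their median (black bar) and the number of genes tested in brackets; red and blue points passed the edgeR test, and the triangle is a bound for c1qc, which had no counts in the mutants. Red points gather in the spliceosome (29 of 55) and erythroid (20 of 25) lists, and all 20 myeloid points lie below 0.

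Genes of the spliceosome, the complex that removes introns, rose in the mutants. Of 55 tested members 29 were higher, none was lower and 26 did not pass, and 36 were higher adjusted over the list alone. The median log2 fold change was 1.18, a 2.27-fold increase (camera adjusted p = 1.21e-19; adjusted p = 0.596 with an estimated correlation; fry adjusted p = 0.0191). PRPF3 (ENSDARG00000086425, chromosome 16, 9541721 to 9562689), a gene of the U4/U6 particle, stood at 291 ± 79.6 CPM in mutants and 24.9 ± 2.06 CPM in wildtypes (SD, n = 3; edgeR adjusted p = 0.00225). PRPF31 (ENSDARG00000095904, chromosome 16, 32128329 to 32136642), of the same particle, stood at 288 ± 81.3 and 22.2 ± 4.50 CPM (adjusted p = 0.00225). SNRPD2, a core protein gene of the snRNPs, was at 277 ± 40.6 and 37.1 ± 3.91 CPM (adjusted p = 0.00225), and XAB2, which also acts in transcription-coupled repair, at 149 ± 40.6 and 16.2 ± 1.32 CPM (adjusted p = 0.00272). These 4 passed without any 1 library. The count of higher members was 16 without mutant replicate 2 or mutant replicate 3, 12 without wildtype replicate 2 and 19 without wildtype replicate 3. Globin genes took a 7.76-fold larger share of counts in the same mutant libraries, and a 12.7-fold larger share without wildtype replicate 3.

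Of 25 DNA damage response genes 6 rose, among them mdm2, sesn3 and cdkn1a, none fell and 19 did not pass. Adjusted over the list alone, 9 were higher. The median was 0.64 (camera adjusted p = 0.00221; adjusted p = 0.596 with an estimated correlation; fry adjusted p = 0.0191). The ligase gene mdm2 (ENSDARG00000033443, chromosome 4, 23404714 to 23415116) stood at 391 ± 73.1 CPM in mutants and 51.7 ± 3.69 CPM in wildtypes (SD, n = 3; edgeR adjusted p = 0.00225). The stress-response gene sesn3 was 5.04-fold higher (adjusted p = 0.00439), and cdkn1a, which encodes the p21 inhibitor of the cell cycle, 2.87-fold higher (adjusted p = 0.0168). CCNG1 and PHLDA3, 2.68-fold and 2.49-fold higher, lie outside the rule for named genes and were chosen after their values were seen. The call of the list ended without mutant replicate 1 (adjusted p = 0.0525). Members higher numbered 3 without mutant replicate 2, mutant replicate 3, wildtype replicate 2 or wildtype replicate 3, where cdkn1a did not pass (adjusted p = 0.0618 to 0.0983). In the same mutant libraries the erythroid median was 7.99-fold higher and the myeloid median log2 fold change -1.08.

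Cell cycle genes were called as lists with few single genes passing. Of 24 genes of S phase and replication, CCNE2, a cyclin gene of S phase entry, rose 5.09-fold and TYMS, a thymidylate synthesis gene, 3.26-fold (edgeR adjusted p = 0.0169 and 0.0483). CDC6 and CDC45, which act at replication origins, were at log2 fold changes of 1.12 ± 0.31 and 1.73 ± 0.48 (SE; adjusted p = 0.0691 and 0.072). The list's median was 0.90, 23 members were positive and 6 were higher adjusted over the list alone (camera adjusted p = 2.09e-05; adjusted p = 0.781 with an estimated correlation). Members higher numbered 0 without mutant replicate 2, mutant replicate 3 or wildtype replicate 2, 1 without wildtype replicate 1 or wildtype replicate 3, and 6 without mutant replicate 1. DESeq2, limma voom and the fit with the replicate number as a block each called 7 higher. Of 25 genes of G2 and mitosis, 23 were positive with a median of 0.68 (camera adjusted p = 0.00289; adjusted p = 0.786 with an estimated correlation). None passed the edgeR test, over all genes or adjusted over the list alone, while 8 had an unadjusted p below 0.05, DESeq2 called 3 and limma voom 6. The call of this list ended without mutant replicate 2 (adjusted p = 0.06) and without wildtype replicate 1 (adjusted p = 0.108). Cell type markers shifted in the same libraries, with the erythroid median 7.99-fold higher and all 20 myeloid genes negative, so these values are not corrected for the mix of cells.

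Among 37 DNA repair and R-loop factors, 2 rose. The helicase gene setx, whose product unwinds RNA from DNA, was at 294 ± 149 CPM in mutants and 42.2 ± 12.7 CPM in wildtypes (SD, n = 3; edgeR adjusted p = 0.0148). The other, rnaseh2c, encodes a subunit of the enzyme that cuts RNA paired with DNA and was 2.96-fold higher (adjusted p = 0.0455). Adjusted over the list alone, 3 were higher, and the list was not called (median 0.27, camera adjusted p = 0.124). Members higher numbered 0 without mutant replicate 2, mutant replicate 3, wildtype replicate 2 or wildtype replicate 3, 1 without wildtype replicate 1 and 5 without mutant replicate 1. DESeq2 called 5 higher, limma voom 7 and the fit with the replicate number as a block 5. Erythroid and myeloid markers shifted in these libraries too (a 7.99-fold higher median and a median of -1.08).

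Red blood cell genes rose in the mutants. Of 25 erythroid genes 20 were higher, none was lower and 5 did not pass, and 23 were higher adjusted over the list alone. The median increase was 7.99-fold (camera adjusted p = 5.82e-13; adjusted p = 0.596 with an estimated correlation). The erythroid transcription factor gene klf1 stood at 210 ± 105 CPM in mutants and 12.4 ± 9.65 CPM in wildtypes (SD, n = 3; edgeR adjusted p = 0.0228). The globin gene hbae5 was at 112 ± 54.4 and 3.77 ± 4.56 CPM (adjusted p = 0.0212), and tspo at 521 ± 263 and 65.2 ± 13.8 CPM (adjusted p = 0.0105). DMTN, a gene of the red cell skeleton, was at 180 ± 91.1 and 21.9 ± 5.58 CPM (adjusted p = 0.0109). All 14 globin genes together took 2.45% ± 1.33 of mutant counts and 0.316% ± 0.250 of wildtype counts (n = 3; two-sided exact permutation p = 0.1, adjusted 0.15). This share was 7.76-fold larger, and 12.7-fold without wildtype replicate 3. Without that library the log2 fold changes of hbae5 and klf1 were 6.60 and 4.70, against 4.89 and 4.08 with it. Erythroid genes higher numbered 2 without mutant replicate 2 or mutant replicate 3, 0 without wildtype replicate 2 and 3 without wildtype replicate 3.

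Thrombocyte genes moved both ways. Of 17 tested, gp9, tubb1, GFI1B, GP1BB and NFE2 rose, FERMT3 (ENSDARG00000030938) fell and 11 did not pass. Adjusted over the list alone, 5 were higher and 5 lower, and the list was not called (median -0.54, mean 0.12; camera adjusted p = 0.839). DESeq2 and limma voom each called 5 higher and 5 lower, and the fit with the replicate number as a block 5 and 3. The surface receptor gene gp9 was 9.54-fold higher and tubb1, a platelet tubulin gene, 9.30-fold higher (edgeR adjusted p = 0.0109 and 0.0244). GFI1B, a transcription factor gene of the erythroid and thrombocyte lineages, was at 105 ± 47.1 CPM in mutants and 26.3 ± 7.03 CPM in wildtypes (SD, n = 3; edgeR adjusted p = 0.0256). FERMT3, which activates integrins, was 3.31-fold lower (adjusted p = 0.0124). GP1BB and NFE2, 7.50-fold and 7.45-fold higher, were chosen after their values were seen. For itga2b, the gene behind the reporter, the log2 fold change was 1.15 ± 0.64 (SE; adjusted p = 0.326). Members higher numbered 1 without mutant replicate 2 or wildtype replicate 3, 0 without mutant replicate 3 or wildtype replicate 2, and 2 without wildtype replicate 1. FERMT3 did not pass without mutant replicate 2, mutant replicate 3 or wildtype replicate 2 (adjusted p = 0.0621 to 0.0771), and 2 members were lower without mutant replicate 1 or wildtype replicate 1. The erythroid median was 7.99-fold higher and the myeloid median -1.08 in these libraries.

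Some myeloid genes fell in the mutants. Of 20 tested, 4 were lower, none was higher and 16 did not pass, and 14 were lower adjusted over the list alone. All 20 were negative, with a median of -1.08, also with c1qc at its bound (camera adjusted p = 4.38e-07; adjusted p = 0.596 with an estimated correlation; fry adjusted p = 0.0557). The myeloid transcription factor gene spi1a stood at 24.4 ± 2.56 CPM in mutants and 69.3 ± 24.6 CPM in wildtypes (SD, n = 3; edgeR adjusted p = 0.0291). The phagocyte oxidase gene cyba was at 67.5 ± 12.2 and 168 ± 43.8 CPM (adjusted p = 0.0312), and LCP1, an actin bundling gene of leukocytes, at 116 ± 12.7 and 293 ± 102 CPM (adjusted p = 0.0372). The complement gene c1qc had 0 counts over the mutants and 71 over the wildtypes, at least 19.0-fold lower with a floor of 3 counts over the group. Myeloid genes lower numbered 0 without mutant replicate 2, mutant replicate 3, wildtype replicate 2 or wildtype replicate 3. DESeq2 called 11 and limma voom 14. Erythroid markers were higher in the same libraries (20 of 25, median 7.99-fold), and no correction for the mix of cells was made here.

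**Figure D3:**
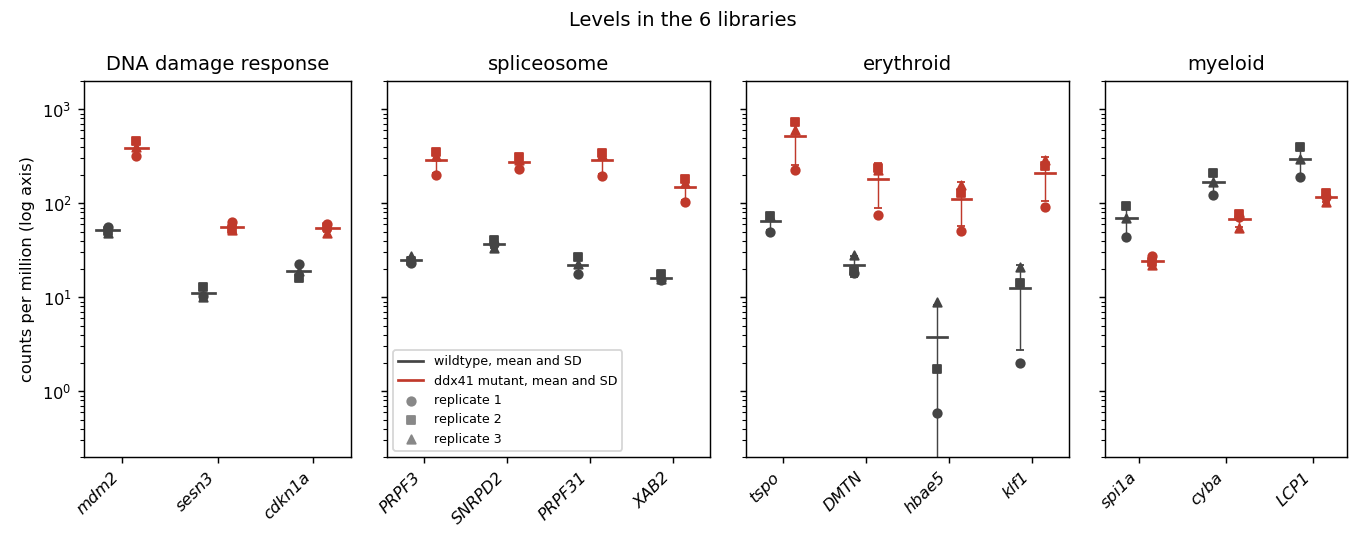
CPM (log axis) in each of the 6 libraries for named genes of 4 lists, wildtype in grey and ddx41 mutant in red, with bars at the mean ± SD (n = 3; the lower bar of hbae5 in wildtype runs off the axis) and a symbol per replicate number. In each gene shown the 3 mutant points lie on one side of the 3 wildtype points, with mdm2 at 391 against 51.7 CPM and LCP1 at 116 against 293 CPM on average. The genes shown were taken from the members of each list with the smallest p, so this separation follows from that choice.

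Some inflammatory and interferon genes changed, and neither list was called. Of 31 genes of the NF-kB and cytokine list, 3 fell: MMP9, a matrix protease gene of neutrophils (3.62-fold), ACOD1, which makes itaconate in phagocytes (3.01-fold), and the receptor gene tnfrsf1b (2.51-fold). Their edgeR adjusted p were 0.0209, 0.0212 and 0.038. The receptor gene tlr4ba rose 5.86-fold (adjusted p = 0.0234). Adjusted over the list alone, 1 was higher and 4 lower, and 21 of the 31 were negative (median -0.25, camera adjusted p = 0.199). Of 26 interferon and nucleic acid sensing genes, isg15 rose to 8.43 ± 6.80 from 0.989 ± 0.389 CPM (SD, n = 3; edgeR adjusted p = 0.0465). TBK1, a kinase gene of innate signalling, fell to 14.9 ± 1.99 from 41.9 ± 4.05 CPM (adjusted p = 0.0182). Adjusted over the list alone, 1 was higher and 1 lower, and 17 of the 26 were negative (median -0.40, camera adjusted p = 0.26). The NF-kB list had 1 gene higher and 5 lower with limma voom, and 1 and 13 without mutant and wildtype replicate 1 together, an alternative chosen after seeing the data. For the interferon list these were 0 and 4, and 1 and 4, and DESeq2 called 1 and 3. With the replicate number as a block, 0 interferon genes were higher, so isg15 did not pass, and 2 were lower. None of these 6 genes passed without mutant replicate 2, mutant replicate 3 or wildtype replicate 2 (adjusted p = 0.0587 to 0.169). Nor did isg15 pass without any other library (0.0947 to 0.0966; log2 fold change 3.07 with all libraries, 2.22 without mutant replicate 1), TBK1 or tlr4ba without wildtype replicate 3 (0.0583 and 0.075), or tnfrsf1b without wildtype replicate 1 (0.0643). Without mutant replicate 1 or wildtype replicate 1, 2 interferon genes were lower. The median of the myeloid markers was -1.08 in the same libraries.

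Genes on the list of blood stem and progenitor transcription factors and receptors also moved both ways. Of 21 tested, CXCR4 (ENSDARG00000041959) and ptprc, which encodes the leukocyte phosphatase CD45, fell, TAL1 rose and 18 did not pass. Among those 18 was the other gene with the symbol CXCR4. CXCR4 (chromosome 9, 10721532 to 10723557) stood at 5.19 ± 0.582 CPM in mutants and 42.5 ± 11.0 CPM in wildtypes (SD, n = 3; edgeR adjusted p = 0.00289), and passed without any 1 library. TAL1, a transcription factor gene of blood progenitors and red cells, was 5.97-fold higher (adjusted p = 0.0262), and ptprc 2.52-fold lower (adjusted p = 0.0263). CBFB, whose product binds RUNX1, was at a log2 fold change of -1.10 ± 0.29 (SE; adjusted p = 0.0606). Adjusted over the list alone, 2 were higher and 3 lower, and the list was not called (median -0.59, camera adjusted p = 0.162). TAL1 and ptprc did not pass without mutant replicate 2, mutant replicate 3, wildtype replicate 2 or wildtype replicate 3 (adjusted p = 0.0679 to 0.128), nor TAL1 without wildtype replicate 1 (0.0542), and 2 members were higher without mutant replicate 1. Alongside, 20 of 25 erythroid genes were higher (median 7.99-fold) and all 20 myeloid genes were negative (median -1.08).

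Some genes of the unfolded protein and amino acid stress response fell in the mutants. Of 23 tested, 4 were lower, none was higher and 19 did not pass, and 5 were lower adjusted over the list alone. The median was -0.67 (camera adjusted p = 0.000239; adjusted p = 0.746 with an estimated correlation; fry adjusted p = 0.0915). PHGDH, the first enzyme of serine synthesis, stood at 11.7 ± 3.42 CPM in mutants and 47.9 ± 2.31 CPM in wildtypes (SD, n = 3; edgeR adjusted p = 0.0109). The cystine transporter gene slc7a11 was 2.97-fold lower (adjusted p = 0.0206). PDIA4 and HSP90B1, which fold proteins in the endoplasmic reticulum, were 2.79-fold and 2.17-fold lower (adjusted p = 0.0295 and 0.046). The count was 0 without mutant replicate 2, mutant replicate 3 or wildtype replicate 2 and 1 without wildtype replicate 3. HSP90B1 also missed the threshold without mutant replicate 1 or wildtype replicate 1 (adjusted p = 0.0574 and 0.0584), and limma voom called 11 genes lower. Myeloid markers were lower as well (median -1.08, all 20 negative) and erythroid markers higher (20 of 25), and no correction for the mix of cells was made here.

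The 13 mitochondrially encoded protein genes took a larger share of counts in each mutant library than in any wildtype library, 3.28% ± 0.232 against 2.06% ± 0.325 (n = 3; two-sided exact permutation p = 0.1, adjusted 0.15). All genes on the mitochondrial genome, ribosomal RNAs included, took 28.2% ± 2.23 and 24.1% ± 3.18 (n = 3; exact permutation p = 0.3), and these shares overlapped. All 13 protein genes were positive, with a median of 0.76 (camera adjusted p = 8.64e-05; adjusted p = 0.778 with an estimated correlation). None passed the edgeR test over all genes, while 12 were higher adjusted over the list alone, 12 had an unadjusted p below 0.05, DESeq2 called 3 and limma voom 9. The overlapping genes mt-atp8 and MT-ATP6 were at log2 fold changes of 1.06 ± 0.30 and 1.04 ± 0.30 (SE; adjusted p = 0.0761 and 0.0832). These libraries also differed in erythroid markers (20 of 25 higher, median 7.99-fold) and myeloid markers (all 20 negative, median -1.08), and the share was not corrected for this. Ribosomal protein genes held 5.36% ± 0.582 and 5.39% ± 0.333 of the counts (n = 3; exact permutation p = 1). None of their 80 genes passed the edgeR test (median 0.15, camera adjusted p = 0.165), with 2 at an unadjusted p below 0.05, 0 called by DESeq2 and 2 by limma voom. The same counts were 1, 0 and 0 for 28 ribosome biogenesis genes (median 0.15, camera adjusted p = 0.414). They were 5, 2 and 4 for 18 genes of the Notch pathway (median -0.29, camera adjusted p = 0.518) and 1, 0 and 1 for 23 immediate early and heat shock genes (median 0.07, adjusted p = 0.561).

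To determine whether other cell types entered the samples, their markers were compared. Of 11 neural genes NEUROD1 and ELAVL3, both of neurons, fell, and 4 were lower adjusted over the list alone (median -2.30, camera adjusted p = 0.0024; adjusted p = 0.778 with an estimated correlation). NEUROD1 was at 1.59 ± 1.11 CPM in mutants and 29.6 ± 13.3 CPM in wildtypes (SD, n = 3; edgeR adjusted p = 0.0116). Without wildtype replicate 1 the list was still called with the preset correlation (median -1.03, camera adjusted p = 0.0329) but not with an estimated correlation (adjusted p = 0.482), and the log2 fold change of ELAVL3 was -1.35 against -2.11 with it. Neural genes lower numbered 1 without mutant replicate 2 and 0 without mutant replicate 3 or wildtype replicate 2. Of 5 lens and retina genes the crystallin genes cryba1b, CRYBA4 and CRYBB1 rose 27.3-fold, 11.8-fold and 11.7-fold, and the list was not called (median 3.55, camera adjusted p = 0.0572). Members higher numbered 1 without mutant replicate 3, wildtype replicate 2 or wildtype replicate 3. The log2 fold change of cryba1b was 4.12 without mutant replicate 1 against 4.77, and that of CRYBB1 5.04 without wildtype replicate 2 against 3.55.

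Endothelial, epidermal and other markers were not called as lists. Of 19 endothelial genes stab2, a scavenger receptor gene, rose 8.37-fold and MRC1, a mannose receptor gene, fell 4.23-fold (edgeR adjusted p = 0.0263 and 0.0479; camera adjusted p = 0.721). Of 17 epidermal genes krt91 fell 3.79-fold (adjusted p = 0.0235; camera adjusted p = 0.313). None of these 3 passed without mutant replicate 2, mutant replicate 3, wildtype replicate 2 or wildtype replicate 3 (adjusted p = 0.0699 to 0.18), nor MRC1 without wildtype replicate 1 (0.0575), and 4 epidermal genes were lower without mutant replicate 1. The medians of the endothelial (0.02), epidermal (0.14) and yolk, liver and gut (0.26) lists were positive where camera's direction was down. No gene passed the edgeR test among 7 of the pronephros (median -0.44, mean 0.07, camera adjusted p = 0.378), 8 of multiciliated cells (median 0.31, adjusted p = 0.305) and 15 of skeletal muscle (median -0.54, adjusted p = 0.199). Nor did any among 9 of neural crest and pigment cells (median -2.19, adjusted p = 0.313) and 12 of yolk, liver and gut (adjusted p = 0.318). In these 5 lists 1, 2, 0, 6 and 0 genes had an unadjusted p below 0.05, DESeq2 called 1, 2, 0, 4 and 0, and limma voom 1, 0, 2, 1 and 1.

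Transcripts of the hatching gland, an embryonic gland that digests the egg envelope, were unevenly spread. The enzyme gene he1.1 stood at 12309 CPM in mutant replicate 1 and 6999 CPM in wildtype replicate 1, and at 424 to 2369 CPM in the other libraries. The fixed list of yolk, liver and gut genes also names he1.1, so that list is not of those tissues alone. With these 2 libraries left out, a choice made after seeing the data, 1702 genes were higher and 1647 lower, including 616 and 362 of those called with all libraries.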

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

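The leaving out of mutant and wildtype replicate 1 together, both high in hatching gland genes, was chosen after seeing the data, as were the tests of other splits of the samples. With DESeq2, 1357 genes were higher and 1223 lower, with limma voom and sample weights 1460 and 1352 (14 lists), and with the 2 libraries left out 1702 and 1647, against 625 and 373 (9 lists) as reported; the cause was not tested. Leaving out each library in turn gave 51 to 1135 genes higher, 11 to 832 lower and 9 to 13 lists, with fewer samples in each fit. RLE size factors (605 and 403), no filter (710 and 507) and the stricter filter (660 and 389) stayed within 1.5 times the reported counts. Camera with an estimated correlation called 0 lists and fry called 2. With the replicate number as a block, 917 genes were higher and 653 lower and 9 lists were called. Deviations of same-numbered libraries correlated at 0.22, 0.16 and 0.09, the last under 0.1, so the numbers were not taken as pairs, although each library correlated best with its own number. Differences of gene class shares moved by less than 1 SD pooled over the genotypes (0.96 points for globin, whose difference was 1.70 to 2.91 points over the libraries left out against 2.14). Of 125 named genes 65 were called, and 9 of them (among them CXCR4 ENSDARG00000041959, mdm2, PRPF3, PRPF31 and zgc:136930) kept their call without any 1 library; 24 of the 65 moved over 1.5 times in fold without some 1 library, and over all alternatives 644 of 842 values kept the call, 198 lost it and 0 reversed. Among genes not called, the log2 fold change of anxa1b turned to -0.0855 with limma voom, -1.11 without mutant replicate 1 (-1.11 to 2.84 over the libraries left out) and -0.229 without the 2 libraries. That of anxa1c turned to -1.36 without mutant replicate 1 (-1.36 to 3.32), that of atp1a1a.4 to -0.891 without mutant replicate 1 (-0.891 to 3.14) and -1.04 without the 2 libraries, and that of rx1 to 0.213 without the 2 libraries; the cause was not tested. The planned ddx41 level was not run. Of 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05, the real split called 625 higher and 373 lower genes and the highest of the others 0 and 0, so 1 split each reached those counts. For lists, 6 of the 10 splits called as many as the real 9, the highest 13. The other splits hold both genotypes on both sides. Their counts of genes and lists are therefore not levels free of a genotype difference. In the simulation, whose adjusted threshold was stricter than that of the real data, 0% of genes with a 2-fold change were recovered.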

Other observations

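The family comparison, the test of crystallins outside the lists, the endothelial and the stem and progenitor comparisons, the estimated correlation for neural genes without wildtype replicate 1 and the counts of other splits were chosen after the results were seen. Genes were grouped by the letters that open their symbols, giving 296 families of at least 8 tested genes among 15050 named genes, and each was tested for a surplus of higher or lower genes by a one-sided Fisher's exact test, adjusted over both directions, which treats genes as independent. The TNF receptor superfamily passed among lower genes, with 4 of 9 members lower (adjusted p = 0.00622, median log2 fold change -1.19). Its members tnfrsf11a and tnfrsf11b, the receptor and decoy receptor of the RANK ligand, were at 8.15 ± 1.36 and 2.80 ± 0.598 CPM in mutants and 31.5 ± 1.89 and 13.2 ± 6.36 CPM in wildtypes (SD, n = 3; edgeR adjusted p = 0.0109 and 0.0329). The others were tnfrsf9b, a costimulatory receptor gene (0.795 ± 0.151 and 8.25 ± 3.66 CPM, adjusted p = 0.0161), and tnfrsf1b. Of the 4 lower members, all but tnfrsf1b, which the fixed rule had named, were named after their values were seen. Of these 4, 0 passed without mutant replicate 2, mutant replicate 3 or wildtype replicate 2 (adjusted p = 0.0587 to 0.165), 2 without wildtype replicate 1 and 3 without wildtype replicate 3. Myeloid markers were lower (median -1.08, all 20 negative) and erythroid markers higher (median 7.99-fold) in the same libraries, so a shift in the mix of cells is not separated from this decrease.

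The other family that passed, among higher genes, was that of SF1 and the SF3A and SF3B genes, with 6 of 10 higher (adjusted p = 0.000216, median 1.16), 9 of the 10 being on the spliceosome list. The SF3A and SF3B proteins belong to the U2 particle, and SF1 binds the branch point of introns before that particle joins. SF3A2, SF3A3, SF3B6, SF3B4, SF3B2 and SF3A1 were higher by 2.48, 2.38, 1.75, 1.83, 1.22 and 1.11 on the log2 scale, and 2 to 6 of them passed without each library in turn. SF3B1, the member most often mutated in myelodysplasia, was at 0.83 ± 0.23 (edgeR adjusted p = 0.0708). Collagen genes did not pass (6 of 48 lower, adjusted p = 0.066). Of the 6 called DNA damage response genes, 5 kept a genotype coefficient above 2 SE with the mean erythroid level as a covariate and 3 with the mean myeloid level. At 3 residual degrees of freedom that bound is too weak to separate an effect of genotype from the mix of cells.

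The median of spliceosome genes, 1.18, lay at percentile 100 of 10000 random lists matched on exonic length and expression, whose largest median was 0.56, which argues against a length bias. With the mean erythroid or myeloid level as a covariate, 22 and 24 of the 29 called genes kept a genotype coefficient above 2 SE, which met the bound set beforehand, but that bound was too weak at 3 residual degrees of freedom: 0 genes stayed called with either, and the median SE rose from 0.287 to 0.513 and 0.792. A larger share of red blood cells or a lower share of myeloid cells therefore cannot be told apart from an effect of genotype (list medians 0.96 and 1.68 with those covariates). A lower myeloid share would raise other cell types alike. The endothelial median, 0.02, was not raised, against 1.18 for the spliceosome list. The stem and progenitor median was -0.59, but that list holds genes also of leukocytes, such as CXCR4 and ptprc. A lower myeloid share could lower these genes, so that list cannot decide. The quartiles did not decide: the stem and progenitor upper quartile, 0.23, lay below the spliceosome lower quartile, 0.54, and the endothelial one, 0.71, above it. An effect of the ddx41 genotype on these genes stays open as a hypothesis.

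The rise of erythroid genes may come from more red blood cells, or their free RNA, among the isolated cells, although isolation by cd41 would be meant to remove them. Scaled to hbbe3 plus hbae3, which stood at 10785 ± 5161 and 6907 ± 3648 CPM in mutants and 749 ± 594 and 1010 ± 757 CPM in wildtypes, 1 of 19 other called erythroid genes stayed higher, klf1 (0.78, edgeR adjusted p = 0.0495), while log2 fold changes ran from -3.01 for RHAG to 1.72 for hbae5 (median -0.49) and none passed as lower. The bound set beforehand was 3 genes. The reference genes rose more than most of the others, as the negative median shows, which left little room to reach that bound. More red cells therefore cannot be told apart from a change of expression within them, and the count of genes does not decide. A lower myeloid share alone would raise other cell types alike, but the endothelial upper quartile, 0.71, lay below the erythroid lower quartile, 2.37. A change of the ddx41 mutants' own blood cell output stays open and was not tested.

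Crystallin and neural genes may reflect other tissue carried into the samples, although isolation by cd41 would be meant to remove it. Of 14 crystallin genes outside the lens list and the named genes, 6 were higher and 12 positive, with a median of 2.88, in line with lens cells or their RNA in the mutant samples, where cryba1b of the lens list averaged 35.7 CPM. Without wildtype replicate 1 the neural median was -1.03 against -2.30 with it, 10 of 11 genes kept their sign, NEUROD1 and ELAVL3 stayed lower (edgeR adjusted p = 0.0252 and 0.0329) and the list was still called with the preset correlation (camera adjusted p = 0.0329), but not with an estimated correlation (adjusted p = 0.482, and 0.778 with all libraries). The median met the bound set beforehand, -1, narrowly, and these values argue against that library alone carrying all of the decrease. A difference of genotype in the tissues themselves stays open and was not tested.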
